A study of Mus musculus with 6 samples.

How the data were processed

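Poly(A) RNA was sequenced from 6 libraries of mouse beige adipocytes grown from preadipocytes of inguinal white fat, immortalized with the large T antigen, in which both Tle3 alleles were floxed and a tamoxifen-inducible Cre recombinase was present. Per the labels' protocols, the cells were differentiated with insulin (20 nM), the thyroid hormone T3 (1 nM), an inducing cocktail and rosiglitazone (1 uM), received either 4-hydroxytamoxifen (500 nM) or ethanol on day 4 for 24 hours, and were harvested on day 10. The ethanol libraries form the control group (n = 3) and the tamoxifen libraries the group labelled TLE3 knockout (n = 3). Nothing says that the replicates were separate cultures or thaws, so the p-values measure the spread between these libraries, which may be technical. No cells without Cre were given tamoxifen in this series, so an effect of the compound or of Cre activity cannot be separated from an effect of the deletion.

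The authors deposited read counts per gene, per the file headers, as whole numbers under Ensembl gene IDs with gene names. Next to them the authors deposited FPKM values that were rounded to whole numbers, which were treated as a score and used only to check the counts. Per the submitters' processing notes, the tools were Novoalign 2.8, Picard and DESeq2 with the mouse build mm9, and their roles and order are not given in the sources used here. Neither the read counter, its annotation nor its strand setting is given in the sources used here, although the library kit was a stranded one per the labels' protocols, so genes that overlap another gene on either strand are uncertain. How reads shared by near-identical genes were counted is also not given. The table lists 13962 genes, and each has at least 10 counts in at least 1 library, so genes below some level had been left out. Of these IDs, 13506 were found in GENCODE M21 and 456 were not; 7 had no name, and 98 rows carried a name that another row also held. Where a listed gene name had several rows, the row with the most counts was used. Coordinates are not printed, because the annotation at hand uses another build than the authors'. The table's row order followed the strength of the group difference (rank correlation of 0.88 with −log10 p over genes, which are not independent), and this order was not used.

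Total counts per library ran from 14606228 to 19294632. As a check, the ratio of counts to rounded FPKM over 392 genes with FPKM of at least 100 was compared between libraries, and it tracked the library totals. Every pair of libraries within a group differed by more than sampling noise (chi-square over genes divided by its degrees of freedom from 2.97 to 7.81), so no library was a second deposit of another; this does not show separate cultures. At these totals, low counts at a few CPM rest on few reads per library and carry sampling noise of their own.

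Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by the package's expression filter with the group as design, which left 13192 genes and set 770 aside, libraries were scaled by TMM factors, and the quasi-likelihood test compared the libraries labelled knockout with the controls in a model with the group alone. P-values were adjusted over all tested genes by the Benjamini-Hochberg method, and a gene was said to rise, fall or change when its adjusted p was under 0.05. CPM values use the TMM-scaled library sizes and are given as mean ± SD. The SE of a log2 fold change was the fold change divided by the square root of the test's F value, and 95% intervals used the test's degrees of freedom. The biological coefficient of variation was 5.25%. Before the data were examined, 42 gene lists were written down for the tissue, the treatment, other cell types and RNA quality; 41 had at least 3 tested members and were tested together with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Each list is also described by how many members rose or fell, with adjustment over all genes and adjusted over the list alone. Some genes stand in several lists, so the lists are not independent of each other.

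The rule for named genes was also written before the data were examined. It took Tle3, the 8 largest rises and 8 largest falls among changed genes with a mean of at least 5 CPM and groups that did not overlap in any library (leaving out unnamed gene models), a fixed set of thermogenic, adipocyte and TLE genes, and from each list up to 4 changed members with the smallest adjusted p, or all changed members if there were 5 or fewer. Where up to 7 members of a longer list moved in 1 direction, they were mostly named too, and this, like the genes of the closing observations, was chosen after their values were seen. A few single genes of the lists are not reported here. For the list members added in this way, calls were recomputed only without each library in turn.

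The scripts were tested on simulated counts for the same comparison of 3 against 3 libraries, with 13073 genes of which 200 were changed, 50 at each size. The test called 50% of the genes changed 1.25-fold, 74% at 1.5-fold, 88% at 2-fold and 96% at 4-fold in the right direction; of 166 genes called, 12 had not been changed. With no change simulated, edgeR called 0 genes. Of 42 simulated lists, all 10 that had been shifted by 0.3 on the log2 scale were called at the preset and at an estimated correlation. Of the unshifted ones 1 and 0 were called. The simulated genes varied independently of each other. The list result therefore does not carry over to lists whose members vary together, such as complex I with an estimated correlation of 0.73.

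Alternatives set before the data were examined were other scalings, other low-count filters, DESeq2 1.42.0, limma-voom, leaving out each library in turn, a replicate block, stricter thresholds, an estimated inter-gene correlation and fry. Offsets for gene length and GC content, made with mgcv 1.9.3 from GENCODE M21 transcripts for 97.1% of the tested genes, were added after the data were seen. No reads were realigned, and no value from the rounded FPKM columns was tested.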

Results

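Beige adipocytes are fat cells within white adipose tissue that can take on the heat-producing program of brown fat. TLE3 is a transcriptional co-repressor of the Groucho family, and the series asked what its deletion does to the transcriptome of such cells once they have differentiated. Gene counts were available for 6 libraries, 3 from ethanol-treated control cells and 3 from cells given 4-hydroxytamoxifen to activate Cre and delete Tle3. Total counts were 17671845, 14832434 and 19294632 in controls 1 to 3 and 15933996, 14606228 and 15137788 in the libraries labelled knockout 1 to 3. On the first principal component, which held 46.3% of the variance, the controls lay between −18.4 and −12.6 and the libraries labelled knockout between 10.2 and 17.3.

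The targeted gene went against its label. Tle3 (ENSMUSG00000032280) was higher in every library labelled knockout, at 286.9, 288.9 and 294.2 CPM, than in the controls, at 151.4, 151.3 and 152.1 CPM. The means were 290 ± 3.76 and 151.6 ± 0.434 CPM (SD, n = 3 per group), a 1.91-fold difference, with a log2 fold change of 0.94 (SE 0.038, 95% interval 0.85 to 1.02; edgeR adjusted p 3.54e-07). An exact two-sided permutation test on CPM gave p = 0.1, the smallest that 3 against 3 libraries allow. The counts cover the whole gene, including exons that a conditional deletion leaves in place, so they do not measure the deleted part and cannot check the labels. For this reason the group is called the libraries labelled knockout throughout, and every direction given here is that of these libraries relative to the controls and rests on the labels. Among the other members of the family, Tle1 (log2 0.22, adjusted p 0.0335) and Tle4 (log2 0.32, adjusted p 0.0157) rose, and Tle2 was at 10.96 ± 3.21 CPM in controls and 14.46 ± 1.88 CPM in the libraries labelled knockout (adjusted p 0.188). The call for Tle1 was lost with DESeq2 (adjusted p 0.0771) and without control 2, control 3, knockout 1, knockout 2 or knockout 3 (adjusted p 0.0636 to 0.12), and that for Tle4 without knockout 3 (adjusted p 0.0828).

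The genes with the largest changes in the libraries labelled knockout, among changed genes with a mean of at least 5 CPM and groups that did not overlap, had varied functions. Flrt1, which encodes a leucine-rich repeat adhesion protein, rose 8.79-fold from 2.68 ± 0.491 to 23.37 ± 4.24 CPM. It was followed by the motor protein gene Myo5b (2.79-fold), the proteoglycan gene Ncan (2.17-fold), the retinoic acid-degrading enzyme gene Cyp26b1, the elastin gene Eln and AW011738 (each 2.1-fold), the lipid droplet gene Cidea (2.06-fold) and the leptin gene Lep (2.05-fold). Dkk2, a secreted modulator of Wnt signalling, fell from 56.77 ± 6.57 to 10.16 ± 1.28 CPM, a log2 fold change of −2.48 (SE 0.105). Further falls were those of Serpinb2 (log2 −1.89), Greb1 (−1.87), Mmd2 (−1.49), the interleukin-1 receptor antagonist gene Il1rn (−1.48), the axon guidance gene Sema3a (−1.36), Fam110c (−1.35) and the monooxygenase gene Fmo2 (−1.33). The edgeR adjusted p of these genes ran from 2.87e-07 to 0.0107. In all, 1629 of 13192 tested genes changed, or 12.3%, with 911 that rose and 718 that fell. Most changes were small, with a median absolute log2 fold change of 0.30; 30 genes rose and 71 fell by at least 2-fold. The changed genes numbered 976 without control 1, 1068 without control 3, 962 without knockout 2 and 621 without knockout 3.

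**Figure D1:**
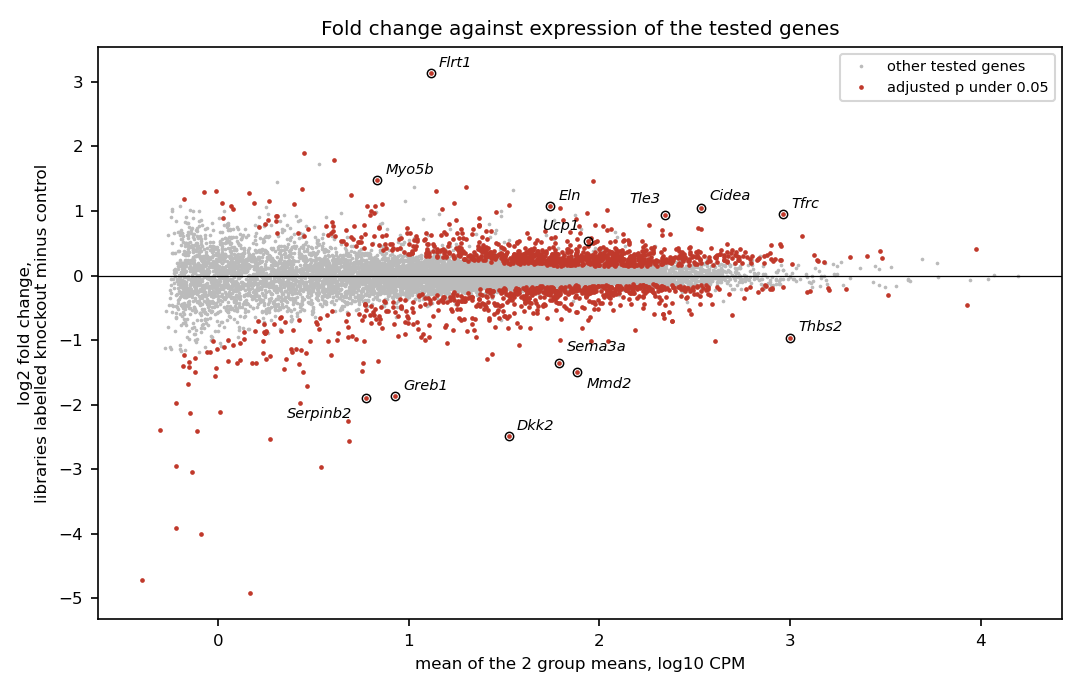
Log2 fold change (libraries labelled knockout minus control, n = 3 each) against mean expression (log10 CPM) of the 13192 tested genes, with the 1629 changed genes in red and 13 genes circled and named. Flrt1 stands highest among the named genes at 3.14 and Dkk2 lowest at −2.48, and Tle3 lies above 0 at 0.94.

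**Figure D2:**
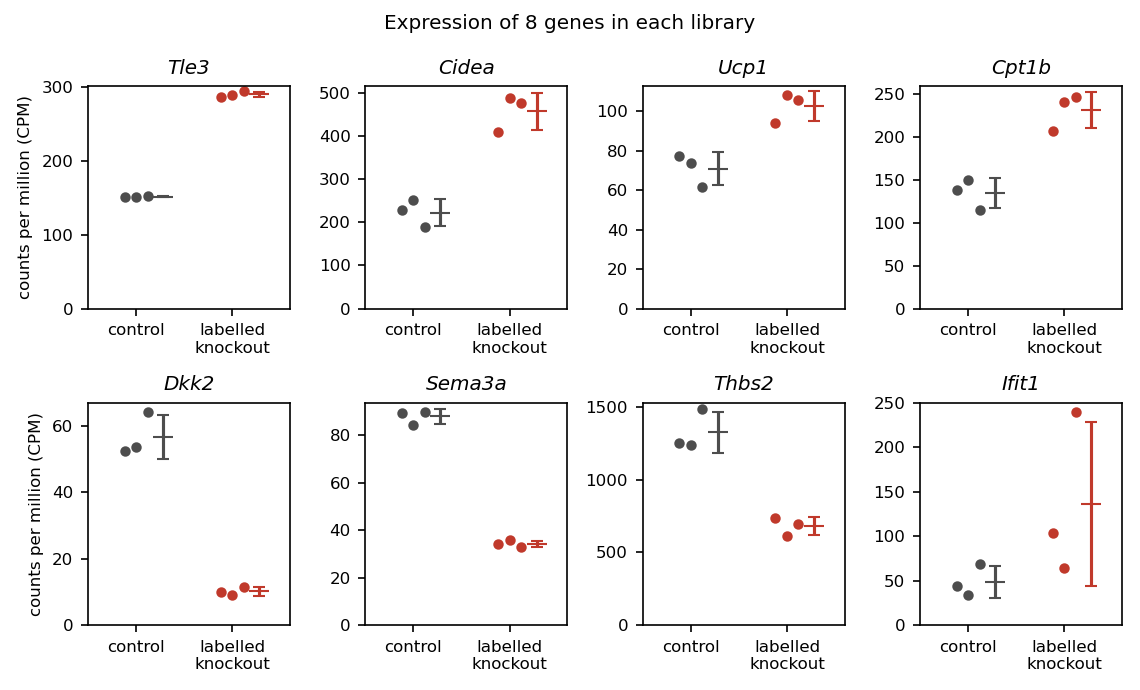
CPM of 8 genes in each library, with the group mean and SD (n = 3) beside the points and axes that start at 0. Tle3, Cidea, Ucp1 and Cpt1b were higher and Dkk2, Sema3a and Thbs2 lower in all 3 libraries labelled knockout than in any control, and the groups overlapped for Ifit1.

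Most thermogenic genes rose in the libraries labelled knockout. Of 29 tested members, 19 rose and 1 fell (21 and 1 adjusted over the list alone), with a median log2 fold change of 0.415. The members that rose numbered 13 without knockout 3, where the median was 0.37, and 16 to 20 without any other library. Ucp1, the uncoupling protein that dissipates the proton gradient as heat, rose 1.45-fold from 70.93 ± 8.35 to 102.9 ± 7.57 CPM (edgeR adjusted p 0.00241). Cidea went from 222.5 ± 31.4 to 457.7 ± 42.8 CPM (adjusted p 0.000119), the muscle-type carnitine palmitoyltransferase gene Cpt1b rose 1.73-fold, Letmd1 1.44-fold and Cpn2 3.47-fold. Ppargc1a, the coactivator gene tied to mitochondrial biogenesis, rose by 0.32 on the log2 scale, Cox7a1 1.4-fold and Cox8b 1.33-fold, and Ebf2, a transcription factor gene of the brown lineage, rose 1.34-fold. Elovl3, a fatty acid elongase gene, was the 1 that fell, from 4.22 ± 0.785 to 2.65 ± 0.454 CPM (adjusted p 0.0469). Prdm16 was at 15.86 ± 1.26 and 18.29 ± 0.144 CPM (adjusted p 0.112) and Dio2 at 1.08 ± 0.355 and 1.52 ± 0.729 CPM (adjusted p 0.426). The list was called by camera at the preset correlation (adjusted p 6.8e-21) and by fry (adjusted p 0.0421). With an estimated correlation the list was not called by camera (adjusted p = 0.384). Its mean was −0.17, −0.13 and −0.30 in controls 1 to 3, and control 3 also had the lowest mean of general adipocyte genes and the highest of fibroblast genes. The call for Elovl3 was lost with DESeq2 (adjusted p 0.0815) and limma-voom (0.0577) and without control 2, control 3, knockout 2 or knockout 3 (adjusted p 0.1 to 0.155).

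Markers that separate beige from other fat cells did not move together. Of 8 tested beige-selective markers only Tbx1 rose, from 10.77 ± 0.149 to 14.09 ± 0.922 CPM (1 adjusted over the list alone as well), and camera gave an adjusted p of 0.802. Of 19 white-selective genes 4 rose and 5 fell (6 and 5 adjusted over the list alone; camera adjusted p 0.301). Lep, Retn (1.57-fold), Orm1 (1.35-fold) and Nr1h3 (log2 0.23) rose, and Agt (log2 −0.42), Nrip1 (−0.31), Fgf10 (−0.44), Zfp423 (−0.33) and Psat1 (−0.15) fell. Of 5 genes of creatine and calcium cycling, Alpl (log2 −0.495) and Slc6a8 (−0.23) fell (0 rose and 2 fell adjusted over the list alone; camera adjusted p 0.129, and called lower by fry with adjusted p 0.0475). The call for Tbx1 was lost without knockout 3 (adjusted p 0.085), that for Slc6a8 without control 3, knockout 2 or knockout 3 (0.0658 to 0.093), and that for Psat1 without control 1, knockout 1, knockout 2 or knockout 3 (0.0727 to 0.129). The call for Nr1h3 was lost without control 1, control 3 or knockout 3 (0.0654 to 0.147) and that for Fgf10 without control 2, control 3, knockout 2 or knockout 3 (0.0644 to 0.124), and the white-selective genes that fell numbered 3 without knockout 2 and 3 without knockout 3.

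Most nuclear genes of the respiratory chain rose, with members in each complex, in the libraries labelled knockout. Over complexes I to IV and ATP synthase, 71 of 93 tested genes rose and 1 fell, with a median log2 fold change of 0.28. In complex I, the NADH dehydrogenase, 33 of 36 rose (36 adjusted over the list alone), among them Ndufs6 (1.35-fold), Ndufb6 (1.33-fold), Ndufa11 (1.31-fold) and Ndufa6 (1.29-fold), and the list median was 0.32. In complex II 3 of 6 rose (6 adjusted over the list alone), namely Sdhb (1.29-fold), Sdhd (1.24-fold) and Sdhc (1.16-fold). In complex III 10 of 12 rose (11 adjusted over the list alone), with Uqcrb at 1.23-fold, and in complex IV, cytochrome c oxidase, 16 of 24 (19 adjusted over the list alone), with Cox5a at a log2 fold change of 0.32 and Ndufa4 at 0.30. In ATP synthase 9 of 15 rose and Atp5g3 fell (10 and 1 adjusted over the list alone), with Atp5j2 at 1.29-fold and Atp5g3 at a log2 fold change of −0.25. Camera adjusted p at the preset correlation was 2.02e-30 for complex I, 0.000149 for II, 1.94e-08 for III, 1.57e-13 for IV and 5.03e-06 for ATP synthase, and all 5 camera calls were lost when the correlation was estimated (adjusted p = 0.384 with an estimated correlation for each). Of the 5, fry called complex I (adjusted p 0.0456) and complex IV (adjusted p 0.0421). Without knockout 3 the members that rose numbered 1 in complex II, 2 in III, 8 in IV and 3 in ATP synthase (where 0 fell), and without knockout 2 they numbered 1, 10 and 5 in complex II, complex IV and ATP synthase. The call for Sdhd was lost without knockout 2 (adjusted p 0.0583) or knockout 3 (0.0778), that for Sdhc without control 1, control 3, knockout 2 or knockout 3 (0.0972 to 0.157), and that for Atp5g3 without knockout 3 (0.0615).

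Transcripts encoded by the mitochondrial genome did not follow the nuclear genes. Of 8 tested mitochondrially encoded genes, edgeR called 0 (0 adjusted over the list alone); 1 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. Their log2 fold changes ran from −0.77, for mt-Nd3 at about 1 CPM, to 0.06 for mt-Nd6. The abundant mt-Nd1 stood at 15790 CPM in controls and 15690 CPM in the libraries labelled knockout (adjusted p 0.952), and mt-Co1 at 11690 and 11780 CPM (adjusted p 0.933). Mitochondrially encoded genes took 6.11%, 6.54% and 6.17% of the counts in controls 1 to 3 and 6.29%, 6.01% and 6.09% in knockout 1 to 3. Camera gave an adjusted p of 0.467 with a median of −0.035 (from −0.057 without control 1 to 0.001 without control 2); with offsets for gene length and GC content, chosen after the data were seen, the list was called lower (adjusted p 0.0194, median −0.12).

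Many genes for mitochondrial fuel oxidation also rose in the libraries labelled knockout. Of 23 genes of the tricarboxylic acid cycle 18 rose (22 adjusted over the list alone), including Sucla2 (1.4-fold), Idh3a (1.39-fold) and Suclg1 (1.28-fold). Sdha, Sdhb, Sdhc and Sdhd also stand in the complex II list, so the rises of Sdhb, Sdhc and Sdhd are counted in both. Of 25 genes of mitochondrial fatty acid oxidation 19 rose and 1 fell (23 and 1 adjusted over the list alone), with Acaa2 at 1.41-fold, Hadh at 1.34-fold and Eci1 at 1.33-fold. The 1 that fell was Cpt1a, the liver-type partner of Cpt1b, with a log2 fold change of −0.30 (adjusted p 0.00802). Of 21 genes of branched-chain amino acid catabolism 9 rose (12 adjusted over the list alone), among them Bcat2 (log2 0.36), Dbt (0.33) and Hibch (0.32). Camera adjusted p was 1.05e-16, 4.81e-15 and 1.65e-07 for the 3 lists (adjusted p = 0.384 with an estimated correlation for each). The members that rose numbered 11 and 12 without control 1 for the cycle and fatty acid oxidation, 10 and 9 without knockout 2, and 5 and 6 without knockout 3, where those of branched-chain amino acid catabolism numbered 4.

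Part of the genes that build and maintain mitochondria rose as well. Of 75 genes of the mitochondrial ribosome 31 rose (53 rose and 1 fell adjusted over the list alone), with Mrpl34 at 1.49-fold, Mrpl46 at 1.31-fold and Mrpl4 at 1.26-fold. Of 31 genes of mitochondrial biogenesis and dynamics 16 rose (20 adjusted over the list alone), including the cristae gene Chchd3 (1.36-fold), the adenine nucleotide carrier genes Slc25a5 (1.32-fold) and Slc25a4 (1.23-fold), and the import gene Timm50 (1.22-fold). The medians were 0.18 and 0.20. Camera adjusted p was 2.39e-16 and 5.18e-10 (adjusted p = 0.384 with an estimated correlation for both). In the same order, 17 and 7 members rose without knockout 2, and 12 and 4 without knockout 3. By contrast, 1 of 45 cytoplasmic ribosomal protein genes rose, Rplp2 at 1.22-fold (0 adjusted over the list alone; camera adjusted p 0.0636). That list was called higher without knockout 1 (adjusted p 0.0269) or knockout 3 (0.0161), and the call for Rplp2 was lost without control 1, knockout 1, knockout 2 or knockout 3 (adjusted p 0.0553 to 0.0899) and with length and GC offsets (0.0694).

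**Figure D3:**
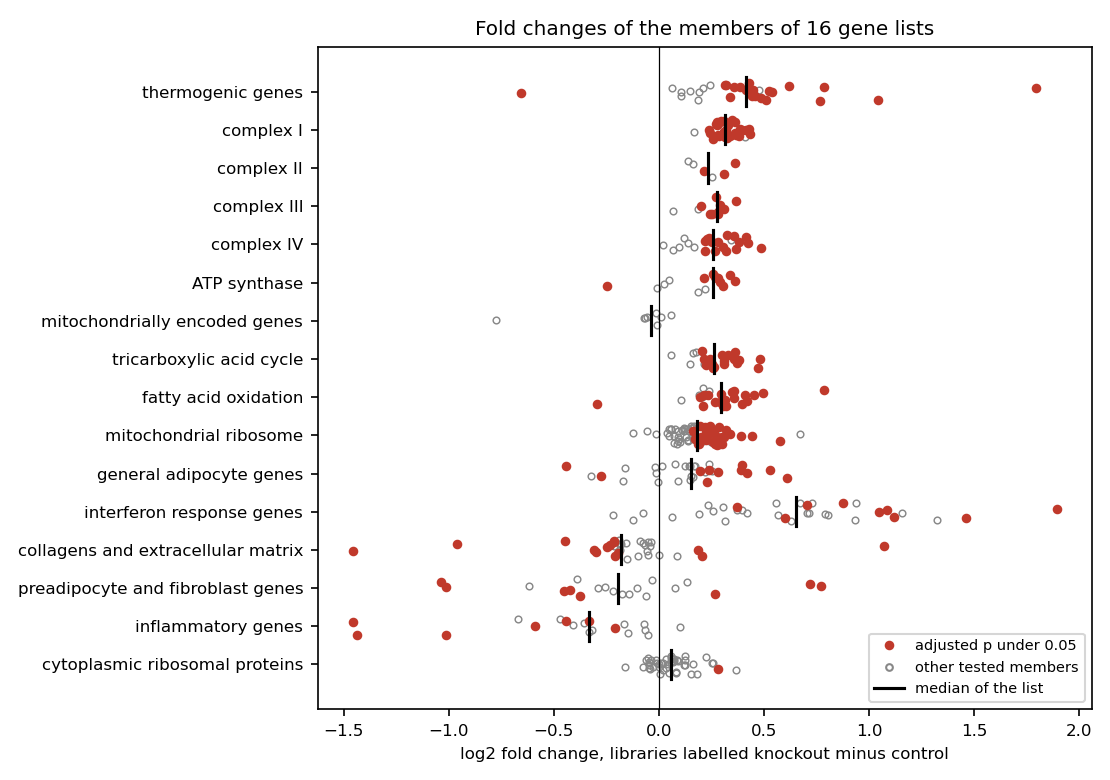
Log2 fold changes (libraries labelled knockout minus control, n = 3 each) of the tested members of 16 lists, with changed members filled in red and each list's median as a bar; the vertical scatter within a list has no meaning. Complex I members lay between 0.17 and 0.43, while the mitochondrially encoded genes were spread around a median of −0.035.

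Some general adipocyte genes rose in the libraries labelled knockout, and most did not pass the threshold. Of 31 tested, 9 rose and 2 fell (11 and 3 adjusted over the list alone), with a median of 0.15, or 0.09 without control 3. Gpd1, which supplies glycerol 3-phosphate, rose 1.53-fold from 912.3 ± 82.1 to 1394 ± 62.0 CPM, Pck1 1.45-fold, the insulin-responsive glucose transporter gene Slc2a4 1.34-fold and the triglyceride synthesis gene Dgat2 1.32-fold; Gpam (log2 −0.44) and Sncg (−0.28) fell. Pparg was at 288.5 ± 27.2 and 322.3 ± 12.4 CPM (adjusted p 0.128), Adipoq at 580 ± 51.2 and 683.5 ± 55.5 CPM (adjusted p 0.0559) and Fabp4 at 4514 ± 657 and 5387 ± 659 CPM (adjusted p 0.165). The list was called higher (camera adjusted p 8.43e-05; adjusted p = 0.573 with an estimated correlation), and its mean was lowest in control 3, at −0.18 against −0.01 in controls 1 and 2. The members that rose numbered 14 without control 2 and 4 without knockout 3. Adipoq passed the threshold with DESeq2 (adjusted p 0.0144) and without control 2 (0.032) or knockout 1 (0.0338), and Pparg did without control 2 (0.0301).

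In other pathways of lipid and glucose metabolism few genes changed. In de novo lipogenesis, Thrsp (1.45-fold), Scd1 (1.33-fold) and Acacb (1.3-fold) rose and Elovl6 (log2 −0.23) fell among 19 genes (3 and 3 adjusted over the list alone; camera adjusted p 0.301). In cholesterol synthesis, 0 of 20 genes rose and 3 fell, among them Sc5d (log2 −0.24) (0 and 4 adjusted over the list alone; camera adjusted p 0.0431, and adjusted p = 0.614 with an estimated correlation). In glycolysis Ldhb rose 1.33-fold, the 1 changed gene among 20 (1 adjusted over the list alone), and the list was called higher (camera adjusted p 0.00238; adjusted p = 0.592 with an estimated correlation). In peroxisomal fatty acid oxidation Eci2 (1.16-fold) and Pex11a (1.13-fold) rose and Abcd2 (log2 −0.27) fell among 17 (11 and 2 adjusted over the list alone; camera adjusted p 0.0264; adjusted p = 0.592 with an estimated correlation). In insulin signalling and glucose uptake 3 of 19 rose, Slc2a4, Igf1 (1.15-fold) and Akt2 (log2 0.175), and 3 fell, Pdk4 (−0.44), Irs1 (−0.44) and Igf1r (−0.21), with 3 and 3 adjusted over the list alone (camera adjusted p 0.981). In lipolysis and adrenergic signalling 4 of 21 rose, namely Adrb1 (1.91-fold), Adora1 (1.26-fold), Prkar2b (1.19-fold) and Lipe (1.18-fold), and Nr4a1 (log2 −0.80) fell (6 and 1 adjusted over the list alone; camera adjusted p 0.0517).

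Several of these smaller calls were lost or gained without 1 library or under another setting. A fit without 1 library has fewer libraries to test with, so a lost call does not show that the library carried the change. The list call was lost for cholesterol synthesis without control 1 (camera adjusted p 0.238), control 2 (0.0588) or knockout 1 (0.31) and with length and GC offsets (0.0767), for glycolysis without control 3 (0.0611), and for peroxisomal fatty acid oxidation without control 1 (0.0832), control 3 (0.115) or knockout 3 (0.0621). Lipolysis and adrenergic signalling was called higher without control 1 (0.0269), control 2 (0.0105) or knockout 1 (0.0123) and with library size alone (0.0342). Glycolysis genes that rose numbered 8 without control 2 and 3 without knockout 1. Peroxisomal genes that rose numbered 6 without control 2, 4 without knockout 1 and 0 without any 1 of the other 4 libraries. Lipolysis genes that rose numbered 7 without control 2, 2 without control 1 or control 3, and 1 without knockout 2 or knockout 3, and insulin signalling genes that rose numbered 1 without knockout 3. The call for Akt2 was lost without control 1, control 3, knockout 2 or knockout 3 (edgeR adjusted p 0.0753 to 0.151) and that for Igf1r without any library other than control 2 (0.0614 to 0.131), and 2 lipogenesis genes other than Elovl6 fell without control 3. The calls for Elovl6, Eci2, Pex11a, Adora1, Prkar2b and Lipe were each lost without knockout 3 (edgeR adjusted p 0.0668 to 0.155), as were those for Scd1 (0.101), Abcd2 (0.0696) and Igf1 (0.0553). They were also lost without knockout 2 for all but Igf1, without control 1 for all but Scd1, Abcd2 and Igf1, without control 3 for all but Scd1, Abcd2, Igf1 and Prkar2b, without knockout 1 for Prkar2b, and without control 2 for Elovl6 (adjusted p 0.0503 to 0.16 over these). With DESeq2 and with length and GC offsets the calls for Elovl6 (0.055 and 0.0663) and Pex11a (0.0667 and 0.0625) were lost, and that for Pex11a with upper-quartile factors (0.0565) and library size alone (0.0532).

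Part of the matrix and fibroblast genes fell in the libraries labelled knockout, and a few rose. Of 33 genes of collagens and extracellular matrix 3 rose and 11 fell (3 and 17 adjusted over the list alone), with a median of −0.18, or −0.10 without control 3. Thbs2, a matricellular glycoprotein gene, fell from 1327 ± 140 to 682.6 ± 62.5 CPM (edgeR adjusted p 8.4e-05), and the matrix metalloproteinase gene Mmp3 (log2 −1.455) and Col5a3 (−0.45) fell as well. Eln, Postn (log2 0.20) and Timp3 (0.185) rose, and Eln doubled from 35.47 ± 5.94 to 74.92 ± 8.01 CPM. Of 20 genes of preadipocytes and fibroblasts 3 rose and 5 fell (3 and 7 adjusted over the list alone), with a median of −0.20, or −0.305 without control 2 and −0.10 without control 3. The small proteoglycan genes Lum (log2 −1.04) and Dcn (−1.01) and the genes Fn1 (−0.45), Thy1 (−0.42) and Pdgfra (−0.38) fell, whereas Nt5e (0.77), the preadipocyte gene Dlk1 (0.72) and Wnt5a (0.27) rose. Camera adjusted p was 4.86e-06 for matrix (adjusted p = 0.384 with an estimated correlation) and 0.00149 for fibroblast genes (adjusted p = 0.542 with an estimated correlation). Matrix genes that fell numbered 5 without control 1, 18 without control 2, 6 without knockout 1, 7 without knockout 2 and 3 without knockout 3, and those that rose numbered 1 in each of these fits. Fibroblast genes that fell numbered 8 without control 2, and those that rose numbered 1 without control 1, control 3, knockout 2 or knockout 3; the fibroblast list's mean was highest in control 3, at 0.256. The calls for Postn and Timp3 were lost without any library other than control 3 (adjusted p 0.0625 to 0.154), that for Wnt5a without any library other than knockout 1 (0.0517 to 0.144), that for Nt5e without control 1, control 3, knockout 2 or knockout 3 (0.0509 to 0.117), and that for Pdgfra without knockout 2 (0.0541) or knockout 3 (0.0589).

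Part of the inflammatory genes fell in the libraries labelled knockout, and no member rose. Of 19 tested, 7 fell (9 adjusted over the list alone), with a median of −0.33 that shrank to −0.16 without control 3, the library with the highest mean of the list (0.338). The acute-phase genes Hp (log2 −1.01) and Saa3 (−1.43), the prostaglandin synthase gene Ptgs2 (−0.59), the chemokine gene Ccl2 (−0.44), the complement gene C3 (−0.33), Csf1 (−0.21) and Mmp3 fell, and Hp went from 148 ± 26.1 to 73.49 ± 8.11 CPM (edgeR adjusted p 0.000442). Of 19 immediate early genes 4 fell (5 adjusted over the list alone), namely Nr4a1 (log2 −0.80), Maff (−0.38), Egr1 (−0.34) and Klf6 (−0.265). Camera adjusted p was 1.88e-07 for inflammatory genes (adjusted p = 0.384 with an estimated correlation) and 0.00666 for immediate early genes (adjusted p = 0.573 with an estimated correlation). The inflammatory genes that fell numbered 4 without knockout 3, the immediate early list lost its call without control 3 (camera adjusted p 0.0611), where 1 member rose, and the call for Egr1 was lost without knockout 3 (adjusted p 0.068). Without knockout 3 the calls for Ccl2 (0.0761), Saa3 (0.051) and Csf1 (0.111) were lost too, as were those for Ccl2 without control 1 (0.0702) and Csf1 without knockout 1 (0.0645).

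Interferon response genes had the highest list median, 0.65, and were spread widely between libraries. Without knockout 3 thermogenic genes had a higher median (0.37) than the interferon response genes (0.34). Of 34 tested, 9 rose (17 rose and 1 fell adjusted over the list alone). Mx1 rose 3.72-fold from 1.17 ± 0.629 to 4.49 ± 3.02 CPM, Ifit1 2.76-fold from 48.77 ± 18.2 to 135.9 ± 92.3 CPM, Isg15 1.84-fold from 53.2 ± 13.7 to 98.3 ± 36.3 CPM and Gbp2 1.52-fold from 46.61 ± 3.46 to 70.94 ± 19.8 CPM, with edgeR adjusted p from 0.0257 to 0.0363. The mean of the list, in log2 units around the mean of all 6 libraries, was −0.37, −0.50 and 0.02 in controls 1 to 3 and 0.37, −0.29 and 0.77 in knockout 1 to 3, so the groups overlapped. Camera gave an adjusted p of 5.84e-07 (adjusted p = 0.585 with an estimated correlation), and DESeq2 called 3 and limma-voom 2 members. The members that rose numbered 0 without control 1, control 2 or knockout 3, 3 without knockout 1 (where 1 fell), 14 without control 3 and 26 without knockout 2, and the calls for Mx1, Ifit1, Isg15 and Gbp2 were each lost without control 1, control 2 or knockout 3 (adjusted p 0.0551 to 0.165), as was that for Isg15 without knockout 1 (0.0781). The calls for Ifit1, Isg15 and Gbp2 were lost with DESeq2 too (adjusted p 0.085 to 0.141), those for Ifit1 (0.0621) and Isg15 (0.0557) with limma-voom, and that for Isg15 with length and GC offsets (0.0575).

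**Figure D4:**
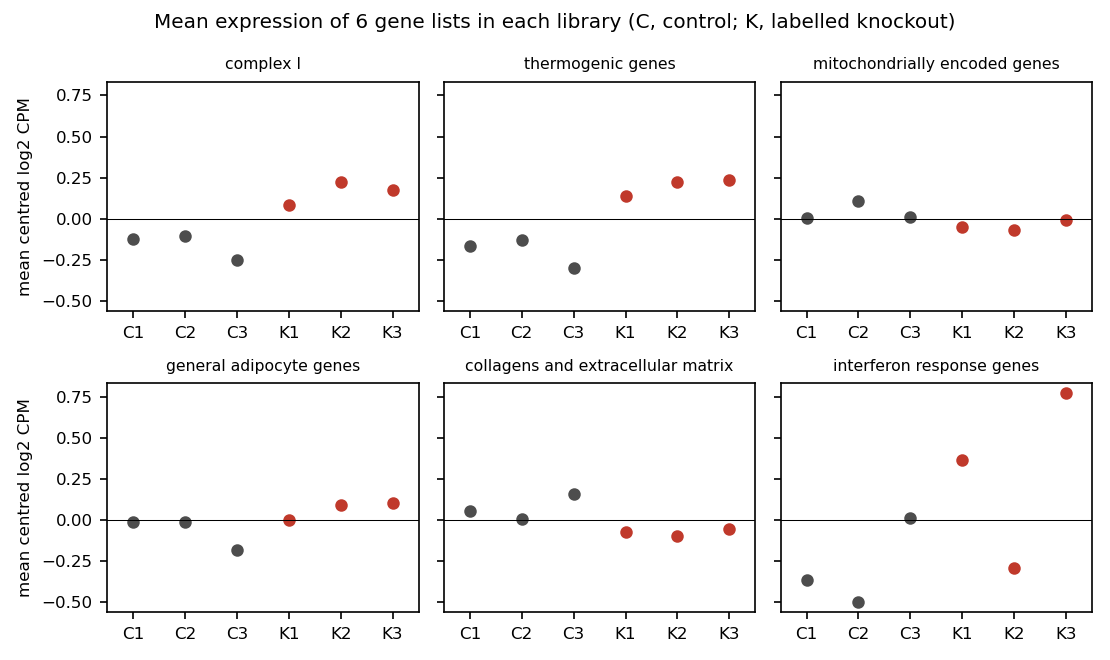
Mean log2 CPM of the members of 6 lists in each library, each gene centred on its mean over the 6 libraries (C1 to C3, controls; K1 to K3, libraries labelled knockout). Complex I and thermogenic genes separated the groups, with complex I at −0.25 to −0.10 in controls and 0.08 to 0.22 in the libraries labelled knockout, and interferon response genes did not, with 0.02 in C3 and −0.29 in K2.

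Lists tied to TLE partners and signalling gave mixed changes in the libraries labelled knockout. Of 19 tested genes of the TLE family and its partner factors, leaving Tle3 itself aside, 4 rose and 2 fell (5 and 2 adjusted over the list alone): Ebf2, the TLE family gene Aes (1.31-fold), Tle4 and Tle1 rose, and Runx1 (log2 −0.34) and Tbx15 (−0.275) fell. The list was called higher (camera adjusted p 0.0147; adjusted p = 0.384 with an estimated correlation). Of 13 Wnt target genes, Sfrp2 rose 1.57-fold and Dkk2 and Wisp2 (log2 −0.32) fell (2 and 3 adjusted over the list alone), and the list was called lower (camera adjusted p 0.00286; adjusted p = 0.384 with an estimated correlation). Dkk2 and Sfrp2 encode secreted modulators of Wnt signalling. Of 4 Notch target genes Notch3 rose 1.23-fold (1 adjusted over the list alone; camera adjusted p 0.283). Because tamoxifen metabolites bind the estrogen receptor, targets of that receptor were listed as well: of 8, Igfbp4 (1.43-fold) and Esr1 (1.2-fold) rose and Greb1, Nrip1 and Xbp1 (log2 −0.24) fell (2 and 3 adjusted over the list alone). Camera did not call these targets (adjusted p 0.129), and fry called them lower (adjusted p 0.0439). Their median log2 fold change was 0.039, with 5 positive and 3 negative values, the lowest that of Greb1 (−1.87). The targets thus did not fall as a set. The partner genes that rose numbered 2 without knockout 3, and those that fell numbered 1 in every fit without 1 library other than control 2. The calls for Wisp2 were lost without control 1, knockout 2 or knockout 3 (adjusted p 0.073 to 0.0969), for Notch3 without control 1, control 3, knockout 2 or knockout 3 (0.0618 to 0.0964), for Tle1 and Tle4 as given above, for Tbx15 without any library other than control 2 (0.0793 to 0.128), for Esr1 without knockout 2 (0.067) or knockout 3 (0.0968) and for Xbp1 without control 1 (0.056) or knockout 3 (0.0694).

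Macrophage and endothelial markers were low and gave no calls, and a few genes shared with muscle changed in the libraries labelled knockout. Of 16 macrophage markers 4 were tested, the highest of which was about 2 CPM in either group, and of 13 endothelial markers 4 were tested; edgeR, DESeq2 and limma-voom called 0 in both, with 1 unadjusted p under 0.05 in each list (0 adjusted over the list alone; camera adjusted p 0.504 and 0.518). Without control 3, 1 endothelial marker rose. None of 13 lymphocyte markers was in the table. Of 16 smooth muscle and myofibroblast genes Des (1.55-fold) and Lmod1 (1.48-fold) rose (2 adjusted over the list alone; camera adjusted p 0.309), and 3 others fell without control 2. Of 6 tested skeletal muscle genes the myoglobin gene Mb rose 1.64-fold, from 259.1 ± 41.9 to 424.2 ± 34.7 CPM, and Neb fell (log2 −0.95), with 2 and 1 adjusted over the list alone (camera adjusted p 0.719); without control 2 those that rose numbered 2.

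Proliferation, damage and stress lists changed little in the libraries labelled knockout. Among 32 cell cycle genes Ccne2 (1.22-fold) and Ccne1 (1.17-fold) rose (0 adjusted over the list alone; camera adjusted p 0.483), and among 22 p53 target and DNA damage genes Phlda3 (1.18-fold), Ccng1 (1.17-fold) and Cdkn1a (1.14-fold) rose (3 adjusted over the list alone; camera adjusted p 0.455). In the unfolded protein and integrated stress response, with 31 genes, Mthfd2 rose 1.11-fold and Xbp1 and Psat1 fell (1 and 2 adjusted over the list alone; camera adjusted p 0.305). Of 25 antioxidant genes 4 rose, the mitochondrial Sod2 (1.34-fold) and Prdx3 (1.28-fold) with Prdx2 (log2 0.18) and Sod1 (0.16), and 4 fell, Gpx3 (−0.72), Hmox1 (−0.42), Gclm (−0.21) and Txnrd1 (−0.18), with 7 and 6 adjusted over the list alone (camera adjusted p 0.802). Of 13 genes often used as references Tfrc, the transferrin receptor gene, rose 1.94-fold from 627.4 ± 99.1 to 1215 ± 41.4 CPM (edgeR adjusted p 0.000183) and 2 fell, among them Gusb (log2 −0.25) (4 and 3 adjusted over the list alone; camera adjusted p 0.473). The call for Ccne1 was lost with DESeq2 (adjusted p 0.0586), with length and GC offsets (0.0577) and without any library other than control 1 (0.0695 to 0.133). That for Ccne2 was lost without control 1, control 3, knockout 2 or knockout 3 (0.102 to 0.16), that for Cdkn1a without knockout 2 (0.0581) or knockout 3 (0.0778) and that for Phlda3 with length and GC offsets (0.0619). That for Mthfd2 was lost in each fit without 1 library (0.0537 to 0.126), with DESeq2 (0.0624) and with the offsets (0.0516). The call for Xbp1 was lost without control 1 (0.056) or knockout 3 (0.0694) and that for Psat1 without control 1 or any library labelled knockout (0.0727 to 0.129). The call for Hmox1 was lost without control 3, knockout 2 or knockout 3 (0.0529 to 0.0761), and that for Gusb without control 1, control 3, knockout 2 or knockout 3 (0.0712 to 0.14). The reference genes that fell numbered 1 without knockout 1 and 0 without control 1, control 3, knockout 2 or knockout 3. The cell cycle list was called lower without knockout 2 (camera adjusted p 0.0441). Antioxidant genes that rose numbered 7 without control 2 and 2 without control 1, knockout 2 or knockout 3, and those that fell numbered 2 without control 1 and 1 without control 3, knockout 2 or knockout 3. The call for Gclm was lost in each fit without 1 library (adjusted p 0.0514 to 0.175), that for Txnrd1 without any library other than knockout 1 (0.052 to 0.169), that for Prdx2 without control 1, control 3, knockout 2 or knockout 3 (0.0514 to 0.115) and that for Sod1 without control 1, knockout 2 or knockout 3 (0.0808 to 0.0991). Without control 2, 4 genes of the stress response fell and 3 reference genes rose, and without knockout 1, 2 reference genes rose.

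Over the 41 lists tested, camera called 22 at the preset correlation, 16 higher and 6 lower in the libraries labelled knockout. With an estimated correlation it called 0, with 3 lists at an unadjusted p under 0.05, and fry, which asks whether a list's members move on balance in 1 direction, called 8. These were thermogenic genes, complex I, complex IV, the mitochondrial ribosome, mitochondrial biogenesis and dynamics and the TLE family with its partners, all higher, and 2 lists that camera did not call, creatine and calcium cycling and estrogen receptor targets, both lower. The medians of these 2 lists were −0.026 and 0.039. Creatine and calcium cycling had 2 positive and 3 negative fold changes, and estrogen receptor targets had 5 and 3.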

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

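The offsets for gene length and GC content were chosen after the data were seen, and the other settings before. The Tle3 level, a log2 fold change of 0.936, stayed past the threshold under every alternative, from 0.92 with library size alone to 0.984 with length and GC offsets, and from 0.926 to 0.946 without 1 library. The changed genes, 1629 in all, numbered from 1288 with DESeq2, where 1083 genes had no adjusted p, to 1693 with upper-quartile factors under the alternatives that kept all 6 libraries, the group-only model and the threshold; 1221 genes were called by both edgeR and DESeq2. Without 1 library they numbered 621 to 1895, with 332 to 1025 changed genes that rose and 289 to 870 changed genes that fell, and 615 of the 621 were among the 1629. The count was 976 without control 1, 1068 without control 3, 962 without knockout 2 and 621 without knockout 3, where fewer libraries were tested. At an adjusted p under 0.05 and at least 2-fold, 101 changed genes were left, 30 higher and 71 lower, and at an adjusted p under 0.01 there were 590, 322 changed genes that rose and 268 changed genes that fell, by the stricter threshold itself. With the replicate block the changed genes numbered 1809. Same-numbered libraries deviated together with correlations of −0.04, 0.19 and 0.03, and 3 of 6 libraries correlated best with their own number. On the second principal component (19.5% of the variance), control 2 (−12.94) and knockout 2 (−12.28) lay together. The other libraries lay between −0.97 and 10.15. The labels give no pairing and these values were mixed, so the numbers were not taken to pair the libraries, and a pairing is not excluded. In that block fit 28 interferon response genes rose and 1 fell, Tle2 (0.0331) and Adipoq (0.0319) passed, lipolysis and adrenergic signalling was called (0.0463), and cholesterol synthesis (0.0599), Elovl3 (0.0553), Mthfd2 (0.0569) and Psat1 (0.0574) did not pass. The gene lists called fell from 22 to 0 with an estimated correlation (0 higher and 0 lower) and to 8 with fry (6 higher and 2 lower), of which 6 were among the 22. The 2 leading lists, at 0.415 for list thermogenic genes and 0.317 for list complex I, kept the call with fry (adjusted p 0.0421 and 0.0456) and lost it with the estimated correlation (adjusted p 0.384 for both). The estimated correlations were 0.261 and 0.73 in place of 0.01, the only setting in which the camera runs differed. Apart from the estimated correlation and fry, lists were recomputed only under some of the alternatives. These were library size alone, a mean CPM of at least 5, the replicate block, length and GC offsets and leaving out each library. Under them 18 of the 22 lists kept their call and 4 lost it in at least 1 setting. The 4 were peroxisomal fatty acid oxidation, cholesterol synthesis, glycolysis and immediate early genes. Of 136 named genes past the threshold, 95 stayed past it under every alternative. The call was lost without at least 1 library for 39 and under another setting only for 2. No named gene or list that had been called reversed its direction. Among lists not called, signs could change, as for the median of de novo lipogenesis (0.037, and −0.006 without control 3). Settings meant for normalized values (another pseudocount, no filter on low values) did not apply, since the table holds counts. At this depth and spread, 1.5-fold changes were recovered in 74% of simulated genes, so smaller changes can be missed.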

Other observations

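The families of the first 2 paragraphs and all tests in this part were chosen after the result was seen, except the length and GC test, whose prediction was written before its result was seen, and the splits of the libraries. Semaphorin genes, which encode guidance and signalling proteins, were mostly unchanged but held 4 of the deeper falls in the libraries labelled knockout. Among 18 tested, Sema3a (log2 −1.36), Sema3d (−1.30), Sema6b (−1.01) and Sema4b (−0.62) fell and Sema4a (0.48) rose, and 13 did not pass. Camera gave an adjusted p of 6.45e-06 over 5 families (adjusted p = 0.0375 with an estimated correlation), but the family was chosen because falling members had been seen, and its median was −0.061, or 0.084 without control 3, so whether the family as a whole is lower stays open; without control 3 or knockout 1, 0 semaphorins rose. All 5 tested genes of secreted Wnt antagonists changed, but not in 1 direction: Dkk2 (−2.48), Sfrp4 (−1.08) and Dkk3 (−0.98) fell and Sfrp1 (0.74) and Sfrp2 (0.65) rose, with camera lower (adjusted p 1.04e-08; adjusted p = 0.0567 with an estimated correlation). The other families were chosen in the same way, so their camera values describe them and do not test them. Of 20 genes of the mitochondrial import machinery 9 rose and 0 fell (camera adjusted p 9.82e-08; adjusted p = 0.209 with an estimated correlation), with Tomm5 at 0.415; 4 rose without knockout 2, 3 without knockout 3 and 6 did so without control 3. Of 38 mitochondrial carrier genes 10 rose and 1, Slc25a24 (−0.46), fell, a weak tendency (camera adjusted p 0.0436, and adjusted p = 0.379 with an estimated correlation). The camera call was lost without control 1 (0.0551), control 3 (0.119), knockout 2 (0.064) or knockout 3 (0.0662). The carrier genes that rose numbered 6, 7, 7 and 4 in these fits, in the same order, and 12 without control 2. Because Dlk1 (0.72), Cdkn1c (1.34) and Rian (1.18) rose, imprinted genes were tested as a group. Camera gave no call for 23 of them (adjusted p 0.595), with Peg10 (−0.595) and Asb4 (−1.23) lower. Rian and Asb4 were below 1 CPM in both groups. In each fit without 1 library 2 imprinted genes rose. Those that fell numbered 3 without control 2 and 1 without any other library.

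Some genes below the level set for named genes fell steeply in the libraries labelled knockout. Ptpn5, a tyrosine phosphatase gene, had 47, 36 and 68 counts in controls 1 to 3 and 2, 1 and 1 in knockout 1 to 3 (edgeR adjusted p 4.29e-05). Spon1, a matrix adhesion gene, had 84, 107 and 125 counts against 7, 16 and 12 (adjusted p 0.000119), and the transporter gene Slco5a1 had 142, 118 and 155 against 26, 22 and 28 (adjusted p 8.3e-06). These genes were picked by eye from the table and were not recomputed under the alternatives.

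Tle3 counts were higher in the libraries labelled knockout, with a log2 fold change of 0.936. Reads shared with Tle1, Tle2, Tle4 and Tle6 are argued against. Their summed level moved by 16.9 CPM, from 74.2 to 91.1 with a pooled SD of 4.52, against a gain of 138 CPM for Tle3. The TLE family gene Aes was not in this sum, and how shared reads were counted is not given. An unchanged transcript that merely keeps its undeleted exons is also argued against, since the lower 95% bound of the log2 fold change was 0.853. An exchange of the 2 groups' labels cannot be told apart from a higher output of a deleted allele, because both allow the value of 0.936 and no counts of the deleted exons were analysed here. A biological candidate explanation is that losing the co-repressor raises transcription or stability of its own truncated message, which was not tested.

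Nuclear genes of mitochondrial proteins were higher in the libraries labelled knockout, with 152 of 243 genes past the threshold upward and a median of 0.254. Without knockout 3 fewer members rose in each of the 9 lists behind this set. They numbered 24 in complex I, 5 in the tricarboxylic acid cycle and 12 in the mitochondrial ribosome, while the 9 list medians ran from 0.176 to 0.32. Gene length and GC content do not account for the rise as a whole, since the median was 0.22 with offsets for both and 132 of the 152 genes were called again. A larger share of adipocytes in the cultures was tested with 30 general adipocyte genes outside the set, which rose by 0.131 on average against 0.238 for the set; the difference grew by 0.107, with a pooled SD of 0.027, which argues against such a share as the whole cause. It may account for part, as the fibroblast and matrix lists had medians below 0 (−0.196 and −0.181, or −0.10 and −0.101 without control 3) and control 3 had both the lowest adipocyte mean (−0.179) and the highest fibroblast mean (0.256). The difference between nuclear and mitochondrially encoded respiratory chain genes was 0.351 higher in the libraries labelled knockout (at least 0.114 there and at most −0.107 in controls). The nuclear lists separated the groups by themselves, so this separation does not test the mitochondrially encoded genes. Of those genes edgeR called 0 of 8, with a mean log2 fold change of −0.115, a median of −0.035 and a lowest value of −0.773 for mt-Nd3 at about 1 CPM. Whether tamoxifen, Cre activity or the deletion lies behind the nuclear rise stays open.

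Interferon response genes had the highest list median, 0.652, in the libraries labelled knockout. Macrophages in the cultures are argued against by the highest mean of a tested macrophage marker there, 2.26 CPM for Cd68, with no marker past the threshold. Against the control range, the rise was not seen in all libraries labelled knockout. The list mean was −0.292 in knockout 2, inside the control range of −0.497 to 0.016. Knockout 1 and knockout 3 were at 0.368 and 0.771. Whether 1 library carries most of the rise stays open. Without knockout 3 the median was 0.338, below the 0.37 of thermogenic genes and close to the halfway value of 0.326. The median's standard error of 0.067 was taken over members, which vary together, and does not measure spread between libraries. The members called numbered 0 without control 1, control 2 or knockout 3, against 26 without knockout 2. In the replicate block fit 28 rose and 1 fell, but the library numbers were not taken to pair the libraries. The list means ranked in the same order of numbers in both groups, with number 2 lowest and number 3 highest. Each library labelled knockout thus lay above the control of its number. Whether the numbers mark pairs is not given, so a pairing is not excluded as a source of the overlap. A response to recombined DNA or to the compound in some cultures is a possible explanation that the design leaves untested.

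The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 1629 changed genes, as the 1 split of the 10 with so many, and the highest of the other splits gave 0 by edgeR, with up to 1263 genes at an unadjusted p under 0.05. In the other splits the treatment difference lies inside the groups and widens their spread. Few calls there are thus likely whenever the real split differs in many genes, and the contrast is not independent evidence. For the lists called by camera at the preset correlation, 3 of the 10 splits gave at least as many as the real 22, and the highest of the others gave 23; that split set control 1, control 3 and knockout 1 against the rest. A high number of lists called at the preset correlation thus also arose from groupings that mix the treatments. Each of these groupings still holds the treatments in unequal shares on its sides, so part of the treatment difference remains in it. They therefore cannot show how many lists camera would call without a treatment difference.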
